A study of Oryza sativa with 12 samples.

How the data were processed

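RNA from rice (Oryza sativa, japonica cultivar Zhonghua 11) was measured on 12 one-colour Agilent arrays, 3 in each of 4 groups. The labels name the groups as developing seeds and flag leaves, each from wild-type (WT) plants and from transgenic line 51, taken at day 10 after fertilization. The transgene is not named in the labels, and no probe was identified for it. The series design states 3 biological replicates per group, and the number of plants behind each RNA is not given in the sources used here. Because marker genes did not match the tissue labels, the arrays are called seed-labelled and leaf-labelled throughout.

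Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 10.7.1.1, which removed spatial and multiplicative trends within each array. The deposited array files give spot brightness in intensity units, as a processed signal and as raw mean and local background signals. Other deposited columns hold Feature Extraction's marks of 0 or 1, for spots well above background, saturated spots and outlier spots. The authors also deposited a matrix of log2 values for 42475 probes, in which all 12 columns share the same distribution of values. The tool behind that matrix is not given in the sources used here, and the matrix served only as an alternative source of values.

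The value used for each probe was log2 of the processed signal minus the 75th percentile of its array, so that 0 is the 75th percentile. Spots marked as outliers were left out, and probes printed more than once were averaged. Each array held 42477 non-control probes, of which 41889 carried a locus in the RAP (Rice Annotation Project) numbering, covering 29689 loci. A probe was tested when it was well above background on all 3 arrays of at least 1 of the groups compared. A gene was represented by its brightest probe. The first digits of a RAP locus give its chromosome, and genome coordinates were not used here.

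Line 51 was compared with WT in each tissue label with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the data.table package (version 1.17.8), and p-values were adjusted over all probes tested by the Benjamini-Hochberg method. A gene was called when its adjusted p was under 0.05. The difference between the 2 changes was tested as an interaction over all 12 arrays. Genes called in both comparisons were counted per direction and compared with chance by Fisher's exact test, two-sided, over the genes tested in both. Errors given after ± beside a log2 change are standard errors of limma with 3 arrays per group, and errors beside a group mean are standard deviations (SD, n = 3). The arrays fill 3 slides of 4. Slide 1 held the 3 WT arrays and replicate 1 of line 51 from the seed label, slide 2 held a pair of line 51 arrays from the seed label and a pair of WT arrays from the leaf label, and slide 3 held replicate 3 of WT and the 3 line 51 arrays from the leaf label. Changes were therefore also computed within slide 1 and within slide 3, and with slide as a block, which for the interaction means slide terms in the fit of all 12 arrays. Slide 2 compares no genotypes within a label. For genes without left-out spots, the block and the slide terms therefore give the same estimated change as the slide alone. It rests on line 51 replicate 1 for the seed label and on WT replicate 3 for the leaf label. Only the errors differ between these fits, so they are not separate checks.

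Where one group was above background on all 3 arrays and the other was not, the fold is an approximate lower bound. It was computed from the mean of the brighter group minus the mean of the dimmer group, after each value of the dimmer group had been raised to the lowest signal among the probes well above background on its array. Such folds are written as "at least", and the bound holds for the reported processing only. A value not above background can still lie over that lowest signal, and it was then left as it was. On seed-labelled WT arrays Os04g0223600 was above background on 0 of 3, yet its 224-fold is the fitted fold (7.81, log2). The bounds are therefore not strict limits. Differences between the changes under the 2 labels were bounded in the same way, where raising the dim groups could only narrow the difference.

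There were 32 gene lists, each defined by words in the product names or by loci. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. In fry, the one-way p tests whether a list's genes move on balance one way, and the mixed p tests whether they change in either direction. Neither compares the list with other genes. Members were also counted with p adjusted over the list alone. Some members share only a word with their list, and they remained in it.

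Genes were named by a rule. For each tissue label it took the 8 largest rises and the 8 largest falls among called genes with a descriptive product name and with all 3 arrays of one group above all 3 of the other. From each list it took up to 3 called members, or where none was called up to 2 with the largest change, given as values. It also took the sucrose transporters SUT1 to SUT5 and the SWEET genes listed by locus, up to 5 genes per kind of sharing between the tissue labels, and up to 4 genes per direction of the interaction. Any other gene named was chosen after its values were seen.

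The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives replaced the 75th percentile by the median or by quantile normalization, the processed signal by normexp background correction with an offset of 50 or by the deposited matrix, and the brightest probe by the mean over probes. Others dropped the filter or required both groups above background, kept outlier spots, used eBayes with a trend, fitted all 12 arrays together, used slide or replicate number as a block, required an adjusted p under 0.01 or at least a 2-fold change, or left out each replicate in turn. A fit of all 12 arrays with slide terms, and lists without the members that share only a word, were added after the data were seen. Marker lists for floral, meristem, anther, root, endosperm and leaf genes used in the check of the tissue labels were added after the seed storage protein and photosynthesis values had been seen.

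The tests were run on simulated data in which 200 genes were changed. In the comparison of the seed-labelled groups, with 23713 genes, 33 of 67 genes changed by a log2 of 1 were called, as were 60 of 67 changed by 2 and 60 of 66 changed by 3. In the comparison of the leaf-labelled groups, with 23969 genes, the counts were 30 of 67, 60 of 67 and 61 of 66. For the difference between them, with 21876 genes, they were 32 of 67, 62 of 67 and 57 of 66. Of the simulated calls, 8 of 161, 9 of 160 and 5 of 156 were of unchanged genes. Simulated noise was drawn independently for each probe and array, without slide effects or correlation between genes. The real arrays were not shown to be free of either, so these counts need not hold for them. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the array files and drew the figures. The number of arrays limits the precision.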

Results

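Transcript levels were measured in 12 RNA samples of rice, 3 for each of WT and line 51 under each of the labels developing seeds and flag leaves. Line 51 is a transgenic line from a study of sucrose loading, yield and grain size, and its transgene is not named in the labels. Each array held 45151 spots, of which 43734 were not controls. Between 79.2% (seed-labelled line 51 replicate 3) and 86.8% (leaf-labelled WT replicate 1) of these were well above background, and 0 spots were saturated. The 75th percentile of the processed signal lay between 2153 and 4339 intensity units. Correlations across probes between arrays of one group ran from 0.983 to 0.991, and probes are not independent replicates.

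Marker genes of tissue identity were examined first, since every comparison rests on the tissue labels. The arrays labelled flag leaves carried transcripts of floral organs, meristems and dividing cells, and the arrays labelled developing seeds carried abundant transcripts of green leaves. All 14 floral organ identity MADS-box genes, which specify the organs of the spikelet, were higher on leaf-labelled arrays, with a median difference of 7.55 (log2) over both genotypes and 7.37 in WT alone. MADS15 (Os07g0108900) had a mean of 4.10 ± 0.05 in leaf-labelled WT and -3.34 ± 0.39 in seed-labelled WT (SD, n = 3). OSH1 (Os03g0727000), a KNOX homeobox gene of the shoot meristem, stood at 3.82 ± 0.20 in leaf-labelled WT and -4.19 ± 0.24 in seed-labelled WT. The 4 KNOX genes differed by a median of 8.87, the 5 anther and pollen genes by 3.79, and the 47 core histones by 3.20, all higher on leaf-labelled arrays by these medians. The 4 root genes differed by a median of 1.20, and 3 of them were higher in leaf-labelled WT.

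Genes of photosynthesis showed the opposite. The small subunit of Rubisco (Os12g0274700), the enzyme that fixes carbon dioxide, had a mean of 6.46 ± 0.17 in seed-labelled WT and -1.35 ± 0.40 in leaf-labelled WT. PsbS (Os01g0869800), a photosystem II protein of photoprotection, stood at 5.41 and -3.69 in the same groups. Over 45 leaf photosynthesis genes the medians of the group means were 5.88 in seed-labelled WT, 5.82 in seed-labelled line 51, 1.67 in leaf-labelled WT and 1.20 in leaf-labelled line 51. The planned list of 94 light reaction genes, 38 of which share only a word with it, differed less. Its medians were 1.64 in seed-labelled WT and -0.99 in leaf-labelled WT, with 31 genes higher in leaf-labelled WT. Of 48 Calvin cycle and photorespiration genes (medians 0.70 and -0.81), 15 were higher in leaf-labelled WT. The 36 endosperm storage protein genes, which include the glutelins and prolamins that fill the grain, were near the floor under both labels, with medians of -9.67 in seed-labelled WT and -9.19 in leaf-labelled WT. Of these, 4 were above background on all 6 seed-labelled arrays and 7 on all 6 leaf-labelled arrays. The 7 endosperm regulators and starch genes had medians of -2.20 in seed-labelled WT and -4.31 in leaf-labelled WT, and the 11 oil body proteins of the embryo -5.91 and -7.64, both higher on seed-labelled arrays, as the labels would have it. Per gene, the medians of leaf-labelled minus seed-labelled WT were -0.22 and -0.04, and 2 of the 7 and 4 of the 11 were higher on leaf-labelled arrays. Each of the 12 arrays correlated better, across probes, with the median profile of its own label, where the lowest correlation was 0.989, than with that of the other label, where the highest was 0.707. The tissue behind each label is therefore treated as unknown, and the differences between WT and line 51 are reported within each label.

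**Figure D1:**
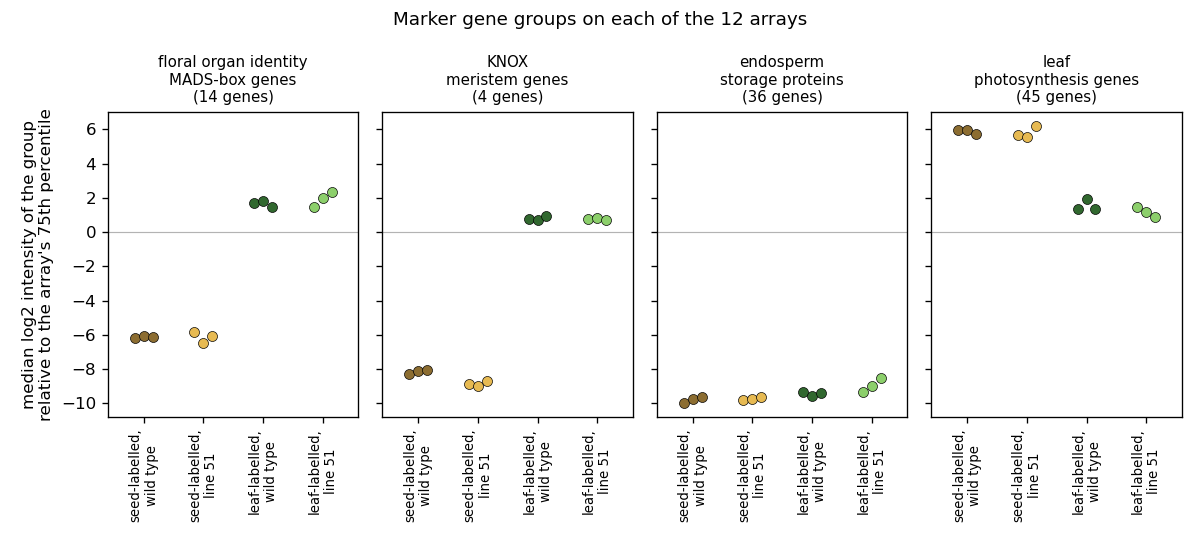
Median log2 signal relative to the 75th percentile of each array (vertical axes) for marker groups on each of the 12 arrays, by group (horizontal axes); each point is 1 array. Floral MADS-box genes are high on the leaf-labelled arrays (group medians 1.70 and 2.10) and leaf photosynthesis genes on the seed-labelled arrays (5.88 and 5.82).

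The comparison of line 51 with WT on the seed-labelled arrays asks which transcripts differed in the transgenic line in the tissue labelled developing seeds. In line 51, a small number of transcripts that were at or near background in WT rose by very large amounts, and fewer genes fell, by less. The transcript of a ribonuclease P-related protein (Os05g0270500), from a family that trims transfer RNA precursors, rose by 10.58 ± 0.19 on the log2 scale, at least 415-fold (adjusted p = 6.66e-06). A gene with an integrase catalytic domain (Os11g0224300), a domain that inserts mobile DNA, rose 371-fold (8.54 ± 0.16, adjusted p = 6.66e-06). An SRA-YDG domain gene (Os07g0435900), whose domain binds methylated DNA, fell by 5.28 ± 0.17 on the log2 scale, a 38.9-fold decrease (adjusted p = 6.42e-05).

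The other large rises among genes with descriptive names were spread over several families. An OB-fold nucleic acid-binding protein (Os03g0429900) rose by 8.90 ± 0.20, at least 105-fold, and an En/Spm-like transposon protein (Os03g0714800) by 7.41 ± 0.89, at least 73.1-fold. A calcium-binding EF-hand protein (Os01g0845900) rose by 7.32 ± 0.33, at least 38.5-fold. An armadillo repeat protein (Os04g0326000) rose by 6.11 ± 0.46, at least 35.1-fold, and a retrotransposon gag protein (Os04g0316700) by 5.86 ± 0.59, at least 18.5-fold. A leucine-rich repeat protein (Os02g0161700) rose 33.7-fold, by 5.08 ± 0.15. Adjusted p-values of these genes ran from 1.78e-05 for Os03g0429900 to 0.0338 for Os03g0714800.

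The other falls among genes with descriptive names were smaller. A BED-type zinc finger gene (Os10g0170600) fell by 2.70 ± 0.30, 6.51-fold, and cycloartenol synthase (Os02g0139500), which makes the first cyclic precursor of plant sterols, fell by 2.13 ± 0.23, 4.39-fold. A pair of cyclin-like F-box genes, of a family that selects proteins for degradation, fell by 2.22 ± 0.26 (Os12g0129700, 4.67-fold) and 1.50 ± 0.15 (Os05g0571700, 2.82-fold). A class I and II aminotransferase gene (Os02g0806900) fell by 2.00 ± 0.25, at least 1.87-fold. An SPX domain gene (Os02g0202200), of a family that senses phosphate status, fell by 1.78 ± 0.19, 3.43-fold. The multifunctional protein of fatty acid beta-oxidation (Os05g0155000) fell by 1.26 ± 0.14, 2.40-fold. The adjusted p-values of these 7 genes lay between 0.0149 (Os05g0571700) and 0.0413 (Os02g0806900).

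In all, 87 of 23712 genes passed the test on the seed-labelled arrays, 65 higher and 22 lower in line 51, and 86 of them differed at least 2-fold. The median size of their change was 2.76 (log2), or 2.75 with the dim genes at their bound. In 40 of them, one group was not above background on all 3 arrays, and 26 of the rises were above background on 0 of the WT arrays. Of all genes tested, 2160 (9.11%) had an unadjusted p under 0.05. All 87 had non-overlapping groups, as did 13.5% of all genes tested, where chance gives 10%. Within slide 1, which held 1 line 51 array, their median signed change was 3.00, against 2.76 over all 6 arrays. Since the groups do not overlap, its sign could not differ. With slide as a block, 30 genes were called, 28 of them among the 87, and of the 16 genes with the largest rises and falls 6 passed, which were Os05g0270500, Os03g0429900, Os11g0224300, Os01g0845900, Os02g0161700 and Os07g0435900. In a fit of all 12 arrays with slide terms 114 genes were called, 58 of them among the 87, and 13 of the 16 passed. Without line 51 replicate 2, 45 genes passed, and without its replicate 3, 48. For 19 called genes other probes of the same gene were tested, and in 17 of them at least 1 passed in the same direction and in 0 in the opposite one. In 5 of the 19 at least 1 other probe did not pass. These probes were not checked for bases in common, so their agreement need not be independent.

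The comparison of line 51 with WT on the leaf-labelled arrays asks the same of the tissue labelled flag leaves. Many of the largest changes were again in the same genes. The EF-hand gene Os01g0845900 rose by 8.06 ± 0.56, at least 78.6-fold (adjusted p = 0.00355), the OB-fold gene Os03g0429900 by 7.45 ± 0.36, at least 40.6-fold (adjusted p = 0.00126), and the integrase gene Os11g0224300 by 7.25 ± 0.14, 152-fold (adjusted p = 6.16e-05). A ZIM domain gene (Os07g0153000), from the family that includes repressors of jasmonate responses, rose 27.4-fold, by 4.77 ± 0.44 (adjusted p = 0.0127), and did not pass with slide as a block (adjusted p = 0.0616, range over the alternatives 0.00658 to 0.785). Of 30 expansins, which loosen cell walls, the beta-expansins Os03g0106900 and Os03g0106500 rose by 4.30 ± 0.32 (at least 4.81-fold) and 3.79 ± 0.25 (at least 6.50-fold), with adjusted p of 0.00482 and 0.00302. The SRA-YDG gene Os07g0435900 fell by 5.80 ± 0.14, 55.5-fold (adjusted p = 0.000104).

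Among the remaining largest rises, the ribonuclease P-related gene Os05g0270500 rose 71.9-fold (6.17 ± 0.23), the En/Spm-like gene Os03g0714800 at least 39.4-fold (6.07 ± 0.33) and the armadillo repeat gene Os04g0326000 at least 14.3-fold (4.58 ± 0.15). A disease resistance protein (Os11g0491600), of a family that detects pathogens, rose by 3.73 ± 0.12, at least 4.53-fold (adjusted p = 0.000352). The other named falls were smaller than that of Os07g0435900. A zinc-binding protein gene (Os02g0172800) fell by 2.14 ± 0.27 (4.40-fold) and a myosin gene (Os06g0488200), a motor protein on actin, by 2.12 ± 0.18 (4.35-fold). The protein kinase genes Os03g0642200 and Os05g0256100 fell by 1.95 ± 0.20 and 1.64 ± 0.18, and a receptor kinase-like gene (Os02g0635600) by 1.31 ± 0.09. The BED finger gene Os10g0170600 fell by 1.62 ± 0.18, and a proline transporter (Os07g0100800) by 1.52 ± 0.16. Adjusted p-values of these falls ran from 0.00329 (Os02g0635600) to 0.0426 (Os02g0172800).

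On the leaf-labelled arrays, 160 of 23969 genes passed the test, 129 higher and 31 lower in line 51, and 139 of them differed at least 2-fold. Their median change was 1.67 (log2), or 1.63 with the dim genes at their bound, and 28 of the rises were above background on 0 of the WT arrays. Of all genes tested, 2295 (9.58%) had an unadjusted p under 0.05. All 160 had non-overlapping groups, as did 16.4% of all genes tested, where chance gives 10%. Within slide 3, which held 1 WT array, their median signed change was 1.73, against 1.67 over all 6 arrays. The sign was again fixed by the groups not overlapping. With slide as a block, 89 genes were called, 68 of them among the 160, and of the 16 genes with the largest rises and falls 8 passed, which were Os03g0429900, Os11g0224300, Os05g0270500, Os03g0714800, Os04g0326000, Os03g0106900, Os07g0435900 and Os02g0635600. The EF-hand gene Os01g0845900 (adjusted p = 0.0715, range over the alternatives 1.92e-05 to 0.0821) and 6 of the 8 falls were among those that did not. In the fit of all 12 arrays with slide terms 89 genes were called, 62 of them among the 160, and 9 of the 16 passed, Os01g0845900 among them (adjusted p = 0.00279). Without line 51 replicate 2, 84 genes passed. Other probes of the same gene were tested for 20 called genes. In 16 of them at least 1 passed in the same direction, in 0 in the opposite one, and in 6 at least 1 did not pass. Bases in common were not checked here either.

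Genes that changed under both labels were compared to ask which differences of line 51 were shared between the 2 RNA sources. Line 51 carried very large changes in the same genes in both. Of the 21877 genes tested under both labels, 38 rose in both where chance gives 0.289 (Fisher's exact test, two-sided, p = 2.94e-76), 7 fell in both where chance gives 0.0243 (p = 1.24e-16), and 0 went in opposite directions. The largest shared rise was in Os03g0115800, a gene with no descriptive name, at least 1360-fold on seed-labelled arrays (11.15 ± 0.66) and at least 2840-fold on leaf-labelled arrays (12.52 ± 0.22). Other very large shared rises were in Os03g0629800, with at least 184-fold and at least 509-fold, and Os04g0510000, with at least 81.1-fold and at least 236-fold. Os04g0223600 rose 224-fold by its fitted change, with 0 seed-labelled WT arrays above background, and at least 43.9-fold. The OB-fold gene Os03g0429900 rose at least 105-fold and at least 40.6-fold. The largest shared falls were in a non-coding transcript (Os08g0100300, chosen after its values were seen), at least 28.7-fold and at least 32.1-fold, and in the SRA-YDG gene Os07g0435900 (38.9-fold and 55.5-fold). Os07g0301000 (25.6-fold and 4.43-fold) and Os06g0363900 (24.5-fold and 5.32-fold), with no annotation, were also chosen after their values were seen. Their means were alike in every group, at 2.31 and 2.36 in seed-labelled WT and -0.80 and -0.73 in leaf-labelled WT. Whether their probes read separate transcripts was not tested, and they are counted as separate genes. The other shared falls included the BED finger gene Os10g0170600 and the F-box gene Os05g0571700, which fell by 1.21 ± 0.07 on the leaf-labelled arrays.

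Over the 45 shared genes the median size of the change was 5.58 (log2) on seed-labelled and 4.57 on leaf-labelled arrays, or 4.84 and 3.82 with dim genes at their bound, and 26 changed by over 4 under both labels, or 20 with dim genes at their bound. In 13 of the 38 shared rises, 0 WT arrays of either label were above background. Other shared genes, chosen after their values were seen, were an esterase/lipase (Os09g0509500, up 5.72-fold and 12.6-fold), an O-methyltransferase (Os05g0515500, up 3.98-fold and 5.32-fold) and a harpin-induced protein (Os04g0677300, up 3.81-fold and 4.98-fold). A flavin-containing monooxygenase (Os04g0223500) was up 11.8-fold and 2.73-fold, and submergence induced protein 2 (Os10g0419400) 17.9-fold and 2.47-fold. Within slide 1 and within slide 3 their median signed changes were 5.55 and 4.22, with signs fixed by groups that do not overlap. Under both labels 18 genes were called with slide as a block and 30 with slide terms in the fit of all 12 arrays, and without leaf-labelled line 51 replicate 2 there were 28.

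**Figure D2:**
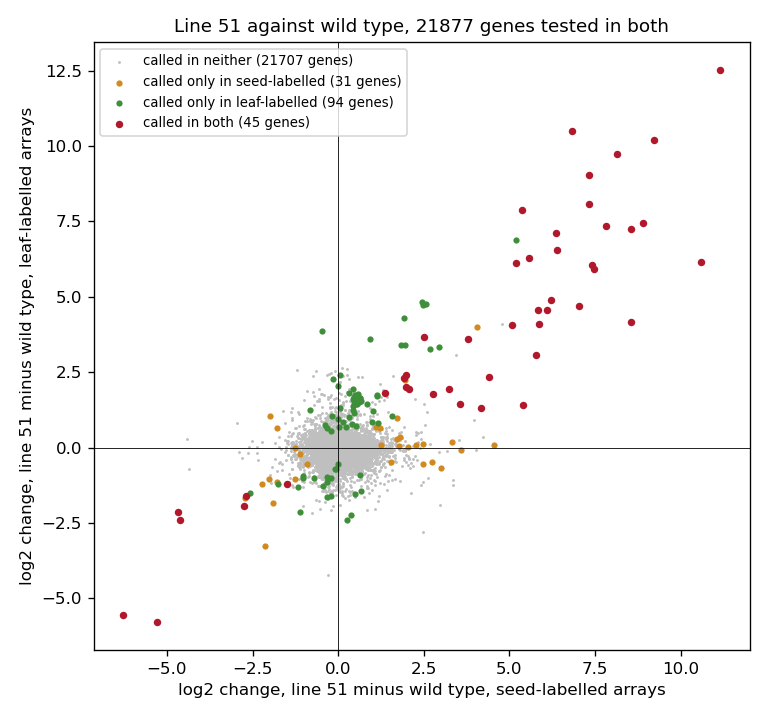
Change in line 51 against WT (log2) on the leaf-labelled arrays (vertical axis) against that on the seed-labelled arrays (horizontal axis), 1 point per gene tested under both labels. The 38 shared rises and 7 shared falls lie in the corners where both changes have the same sign, and 0 genes were called in opposite directions.

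The interaction asks which changes differed in size between the labels. The ribonuclease P-related gene Os05g0270500 rose more on seed-labelled than on leaf-labelled arrays, with a fitted difference of 4.41 ± 0.31 (log2, adjusted p = 0.000199), or at least 2.53 with the seed-labelled WT group at its bound. A DUF6 domain gene (Os04g0422300) also rose more there, by a fitted 4.40 ± 0.59 (adjusted p = 0.0219), or at least 2.51 at the bound of its WT group, which was above background on 0 of 3 seed-labelled arrays. A non-coding transcript (Os07g0457200) and a conserved hypothetical gene (Os05g0296200) had fitted differences of 4.49 ± 0.65 (adjusted p = 0.0297) and 3.97 ± 0.23 (adjusted p = 0.000152), or at least 3.65 and 3.92 at their bounds. In the other direction, an aldo/keto reductase gene (Os10g0114300), of a family that reduces aldehydes and sugars, had a fitted difference of -4.34 ± 0.52 (adjusted p = 0.0114), or -2.42 with its dim leaf-labelled WT group at the bound, with a change of -0.48 on seed-labelled arrays and a rise of at least 3.83-fold on leaf-labelled arrays. Os04g0397900, with no annotation, rose under both labels, with a fitted difference of -3.67 ± 0.48 (adjusted p = 0.0193) that has no bound, since WT was above background on 0 arrays under both. The aminotransferase gene Os02g0806900 had a fitted difference of -3.05 ± 0.48 (adjusted p = 0.0399), or -1.96 with its dim groups at the bound, and the conserved hypothetical gene Os01g0259900 one of -2.67 ± 0.27 (adjusted p = 0.00462).

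Of 21875 genes tested for the interaction, 39 passed, 27 with the larger signed change on seed-labelled arrays and 12 on leaf-labelled arrays, and 2081 (9.51%) had an unadjusted p under 0.05. Of the 39, 23 had the same sign under both labels. In 16 of them at least 1 group was not above background on all 3 arrays, and for 13 of these a bound could be had. Genes of known function among them, chosen after their values were seen, included raffinose synthase (Os08g0495800), an enzyme that makes galactosyl sucrose sugars, with changes of 1.53 and -0.47 (adjusted p for the difference 0.0327), and the proline transporter Os07g0100800, with a difference of 2.02. A disease resistance gene (Os06g0163900) differed by 3.14 (adjusted p = 0.0073), and the blue light receptor gene NPH1-1 (Os12g0101800) by -1.52, with changes of 0.43 and 1.94. With slide terms 12 genes passed, 5 of them among the 39, and the differences of the 8 genes given first lay between -3.48 and 4.96 and kept their signs, with Os05g0270500 and Os05g0296200 past the test, while raffinose synthase, the proline transporter, Os06g0163900 and NPH1-1 did not pass. Over the 34 that no longer passed the median size was 2.15 with and without the terms, and the median standard error 0.419 with them and 0.303 without. Without single replicates the count ran from 12 (without seed-labelled line 51 replicate 2) to 70 (without seed-labelled line 51 replicate 1).

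Sugar transporters and grain genes were examined because the series concerns sucrose loading and grain size. Of the SUT and SWEET genes taken by locus, 0 of 6 tested on seed-labelled arrays and 0 of 7 on leaf-labelled arrays passed limma's test over all genes, with 0 and 2 at an unadjusted p under 0.05. SUT1 (Os03g0170900), the main transporter that loads sucrose across the plasma membrane, had a change of 0.51 ± 0.30 on seed-labelled arrays (means 1.74 ± 0.46 in WT and 2.25 ± 0.42 in line 51, adjusted p = 0.694, within slide 1 a change of 0.16). On leaf-labelled arrays its change was 1.66 ± 0.32 (means -2.13 ± 0.56 and -0.47 ± 0.34, adjusted p = 0.169, within slide 3 a change of 1.11), and it passed when adjusted over the list alone. Over the alternatives its limma adjusted p there ranged from 0.0306 to 0.745, and it passed in 1 of 19. SUT2 (Os12g0641400) had changes of 0.29 ± 0.13 and 0.01 ± 0.14, and SUT4 (Os02g0827200) of 0.0024 ± 0.15 and 0.09 ± 0.11. SUT5 (Os02g0576600) was tested only on leaf-labelled arrays, at 0.05 ± 0.47, and SUT3 (Os10g0404500) under neither label. SWEET15 (Os02g0513100) had changes of -0.60 ± 0.36 and -0.93 ± 0.25, and SWEET4 (Os02g0301100), which exports hexoses into the filling grain, of 0.45 ± 0.25 and 0.02 ± 0.11. SWEET14 (Os11g0508600) was tested on seed-labelled arrays, at 0.62 ± 0.52, and SWEET11 (Os08g0535200), a sucrose exporter of the developing grain, on leaf-labelled arrays, at -0.11 ± 0.13.

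**Figure D3:**
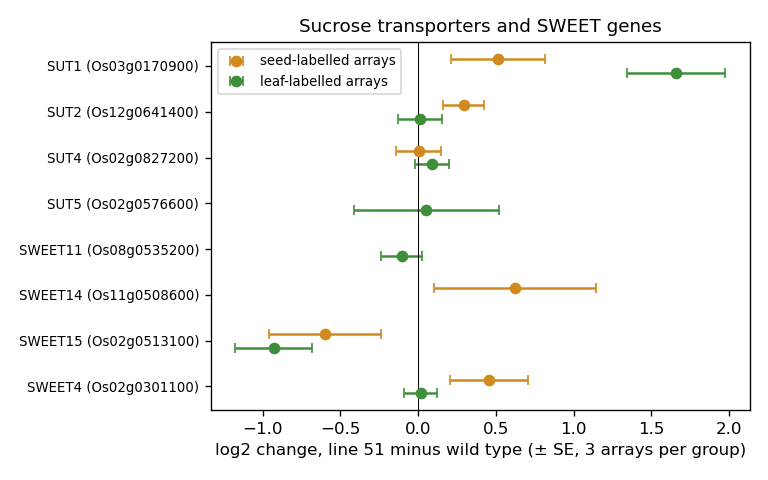
Change in line 51 against WT (log2, horizontal axis) of the sucrose transporters and SWEET genes tested, by tissue label; points are limma estimates from 3 arrays per group and bars are standard errors. SUT1 on leaf-labelled arrays has the largest change, 1.66, with an adjusted p of 0.169.

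On the seed-labelled arrays, 0 of the 28 lists tested passed camera at the preset correlation, where the smallest adjusted p was 0.719 and 1 list had an unadjusted p under 0.05. With an estimated correlation 0 passed (smallest adjusted p = 0.767 with an estimated correlation), and by fry's one-way p 0 passed (smallest adjusted p = 0.710). By fry's mixed p, 6 lists passed. The list with the smallest camera p was starch synthesis: 0 of 20 genes passed over all genes, 2 rose when adjusted over the list alone, and the median change was 0.17. Its unadjusted p by limma's camera was 0.0274 and its mixed adjusted p by fry was 0.018. Its large subunit of ADP-glucose pyrophosphorylase (Os05g0580000), which makes the glucose donor of starch, had a change of 1.12 ± 0.85, and the small subunit (Os09g0298200) one of 0.96 ± 0.25 (adjusted p = 0.351). The 68 genes of cellulose and cell wall remodelling had a median of 0.07, with 0 past the test over all genes and 2 that rose when adjusted over the list alone (fry's mixed adjusted p = 0.00346), and a pectinesterase (Os07g0607400) had a change of 3.36 ± 0.59 (adjusted p = 0.14). Of 272 defence proteins 1 rose over all genes (Os06g0163900, 3.33 ± 0.28, 10.0-fold, adjusted p = 0.00714) and 2 when adjusted over the list alone (fry's mixed adjusted p = 0.0397). Of 60 WRKY transcription factors 1 rose by either count (WRKY30, Os08g0499300, 1.79 ± 0.22, 3.46-fold, adjusted p = 0.0392). Of 41 genes of the Calvin cycle and photorespiration 1 rose by either count, a phosphoribulokinase/uridine kinase (Os04g0280200, 1.73 ± 0.17, 3.31-fold; fry's mixed adjusted p = 0.0263), a name that covers both a Calvin cycle enzyme and a pyrimidine salvage enzyme. Os06g0163900, WRKY30 and Os04g0280200 did not pass with slide as a block (adjusted p = 0.127, 0.346 and 0.0698), and over the alternatives their adjusted p ranged from 7.72e-05 to 0.127, from 0.000788 to 0.346 and from 0.000165 to 0.109. In the fit of all 12 arrays with slide terms Os06g0163900 and Os04g0280200 passed and WRKY30 did not.

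Of 338 genes in the cell cycle list, 2 fell over all genes, and 1 rose and 2 fell when adjusted over the list alone (fry's mixed adjusted p = 0.00739). The ones that fell over all genes were the F-box genes Os12g0129700 and Os05g0571700, neither of which passed with slide as a block and both of which passed with slide terms in the fit of all 12 arrays, and 361 of the 426 listed genes share only the cyclin-like F-box name with the cell cycle. Among 11 genes of senescence and chlorophyll breakdown 1 rose when adjusted over the list alone (median 0.09, fry's mixed adjusted p = 0.0101), as did 1 of 22 expansins (median -0.05) and 1 of 38 genes of nitrogen uptake and assimilation (median -0.07). The nitrate transporter Os10g0111700 had a change of 2.12 ± 0.30 (adjusted p = 0.0678), and the expansin EXPA2 (Os01g0823100) one of 4.01 ± 1.31 (adjusted p = 0.458). WT was above background on 1 of 3 arrays for EXPA2, and its fold at the bound was 6.07.

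In the other seed-labelled lists 0 members passed, either over all genes or adjusted over the list alone. Medians were 0.43 over 14 SWEET genes, 0.16 over 14 amino acid transporters, 0.13 over 15 monosaccharide transporters, 0.18 over 9 genes of trehalose metabolism and 0.04 over 28 of sucrose synthesis and cleavage. They were 0.07 over 64 auxin response genes, 0.05 over 37 of the abscisic acid and dehydration response, 0.12 over 8 of gibberellin metabolism and 0.05 over 20 of the phosphate starvation response. The SPX domain gene Os02g0202200, which fell 3.43-fold, is not among these 20, since its product name did not match the words of the list. The 7 grain size genes had a median of -0.03, and GS5 (Os05g0158500), a serine carboxypeptidase that promotes grain width, had a change of 0.89 ± 0.24 (adjusted p = 0.366). The median was -0.05 over 44 core histones, -0.07 over 147 heat shock proteins, -0.13 over 9 circadian clock genes, and -0.05 over 157 cytosolic ribosomal proteins, whose median within slide 1 was 0.17. It was 0.05 over 15 genes of chlorophyll synthesis, -0.06 over 74 of the photosynthetic light reactions, -0.06 over 79 peroxidases and glutathione transferases, -0.03 over 8 of starch breakdown and 0.09 over 18 embryo and aleurone markers. Lists too short to test gave medians of 0.29 over 3 sucrose transporters, -0.11 over 4 seed storage proteins, -0.17 over 3 cytokinin genes and -0.28 for 1 phloem marker. In 7 seed-labelled lists the median was negative while the mean and camera's direction were positive: grain size genes (mean 0.27), expansins (0.27), defence proteins (0.04), WRKY factors (0.11), peroxidases and glutathione transferases (0.08), light reactions (0.08) and cell cycle (mean 0.0014, median -0.0025).

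On the leaf-labelled arrays, 0 of the 29 lists tested passed camera at the preset correlation, where the smallest adjusted p was 0.0977 and 5 lists had an unadjusted p under 0.05. With an estimated correlation 0 passed (smallest adjusted p = 0.875 with an estimated correlation), by fry's one-way p 0 passed (smallest adjusted p = 0.534), and by fry's mixed p 6 passed. Among 47 core histones the median was 0.11 and 43 were positive, with 0 past either count (camera adjusted p = 0.0977). The 40 genes of the abscisic acid and dehydration response had a median of -0.17, with 0 past the test over all genes and 2 that fell when adjusted over the list alone (camera adjusted p = 0.0977, fry's mixed adjusted p = 0.0214), and a late embryogenesis abundant protein (Os08g0327700) had a change of -2.08 ± 0.54 (adjusted p = 0.333). Of 14 amino acid transporters 1 fell by either count, the proline transporter Os07g0100800 (median -0.28, camera adjusted p = 0.0982, fry's mixed adjusted p = 0.00786). Of 96 peroxidases and glutathione transferases 1 fell by either count, a glutathione transferase (Os10g0368100, -0.89 ± 0.11, adjusted p = 0.0372; list median -0.11). Of 30 expansins, 2 rose by either count, the beta-expansins named above (median -0.09, mean 0.14, fry's mixed adjusted p = 0.00013). Of 261 defence proteins 1 rose by either count, Os11g0491600 (median -0.01, fry's mixed adjusted p = 9.93e-05), and of 361 genes in the cell cycle list 1 fell, the F-box gene Os05g0571700 (median 0.0065, fry's mixed adjusted p = 9.93e-05). The expansins and Os11g0491600 passed with slide as a block, and Os07g0100800, Os10g0368100 and Os05g0571700 did not. With slide terms in the fit of all 12 arrays Os05g0571700 also passed.

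Of the other leaf-labelled lists, SUT1 among 4 sucrose transporters (median 0.07) rose when adjusted over the list alone. The 1 phloem marker measured had a change of 0.35 (adjusted p = 0.44 over all genes), and a list of 1 gene has no adjustment of its own. In all others 0 members passed either count. The 9 SWEET genes had a median of -0.01 and passed by fry's mixed p (adjusted p = 0.0421). Medians were -0.17 over 12 monosaccharide transporters, -0.02 over 28 genes of sucrose synthesis and cleavage, -0.07 over 9 of trehalose metabolism, -0.0051 over 22 of starch synthesis and -0.17 over 8 of starch breakdown. A sucrose phosphate synthase (Os11g0236100), which makes the precursor of sucrose, had a change of -1.48 ± 0.34 (adjusted p = 0.258). Medians were -0.14 over 81 genes of the photosynthetic light reactions, -0.04 over 48 of the Calvin cycle and photorespiration, -0.07 over 15 of chlorophyll synthesis, 0.05 over 11 of senescence and chlorophyll breakdown and -0.02 over 9 circadian clock genes. They were -0.12 over 35 genes of nitrogen uptake and assimilation, -0.03 over 18 of the phosphate starvation response, -0.06 over 85 auxin response genes, -0.12 over 3 cytokinin genes and -0.02 over 9 of gibberellin metabolism. The 11 grain size genes had a median of 0.0081, and GS3 (Os03g0407400), a negative regulator of grain length, had a change of 0.49 ± 0.29. The remaining medians were 0.03 over 51 WRKY factors, -0.01 over 150 heat shock proteins, 0.02 over 158 cytosolic ribosomal proteins, -0.00091 over 81 genes of cellulose and cell wall remodelling, -0.07 over 17 embryo and aleurone markers and -0.02 over 9 seed storage proteins. The median differed in sign from the mean or from camera's direction in 8 lists: cell cycle, expansins, starch synthesis, senescence, gibberellin metabolism, seed storage proteins, SWEET genes and, where camera was not run, cytokinin genes. In expansins, starch synthesis and seed storage proteins the mean and camera's direction were positive, in cell cycle both were negative, in senescence only camera's direction was negative, and in gibberellin metabolism, SWEET and cytokinin genes only the mean was positive.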

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

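The count of genes and the test of it below were fixed before their results were seen, and the bounds on the differences and the test of slides were added after. The results given here are those where the change in line 51 itself differed between the seed-labelled and leaf-labelled arrays by a test of the difference.

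On the limma interaction 39 genes differed. The fitted differences of log2 change, seed-labelled minus leaf-labelled, were 4.41 for the ribonuclease P-related gene Os05g0270500, 4.49 for the non-coding transcript Os07g0457200, 4.40 for the DUF6 gene Os04g0422300 and 3.97 for Os05g0296200. They were -4.34 for the aldo/keto reductase gene Os10g0114300, -3.67 for Os04g0397900, -3.05 for the aminotransferase gene Os02g0806900 and -2.67 for Os01g0259900. With dim groups raised to the floor they were at least 2.53, 3.65, 2.51 and 3.92 for the first 4 genes, and -2.42 and -1.96 for Os10g0114300 and Os02g0806900. For Os04g0397900 no bound can be had, and for Os01g0259900 none is needed. Of the 39, 23 had changes of the same sign under both labels.

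Genotype was reassigned within each label in 100 assignments, the real one and others drawn at random, and 3 of them, the real one included, gave 39 or more genes, a share under 0.05. Such assignments also break the differences between genotypes within each label, so the count excludes chance only against no genotype difference at all, not against equal changes under both labels. The highest other count was 44, from an assignment that kept the real division of the leaf-labelled arrays with the genotypes turned round and exchanged 1 WT with 1 line 51 array among the seed-labelled ones, and the remaining one, with 41 genes, was of the same kind. The assignment with 41 genes keeps the slide 2 arrays together, so it follows the slides as closely as a division into 3 and 3 can, and so does the real one among the seed-labelled arrays. With slide terms 12 genes passed, 5 of them among the 39. The differences with slide terms had the same sign in 39 of 39 genes, exceeded 2 standard errors in 39 and had a median size of 2.21, against 2.20 without the terms. The 39 were selected on the same arrays, and a call needs the arrays of a group to agree across slides. The selection favours this outcome, so it cannot decide on a difference between slides. For the 34 that no longer passed, the median size was 2.15 with and without the terms while the median standard error went from 0.303 to 0.419, so the calls ended through wider errors. Since both assignments keep the real division under one label, they still hold the leaf-labelled difference between genotypes. No biological explanation of the difference between labels was tested, and a difference between the tissues themselves stays open.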

How the results depend on the processing

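The all-array fit with slide terms and the lists without members that share only a word were chosen after the data were seen. Counts stayed within 1.5 times the reported ones, or lists on the same side of the threshold, under 14 of 21 alternatives for the seed-labelled comparison, 13 of 21 for the leaf-labelled one, 22 of 27 for the genes shared, 11 of 25 for the interaction, and 16 and 15 of 21 for the seed-labelled and leaf-labelled lists. The 58 named changes past the test kept their direction in all 1072 comparisons and the test in 857 of them. Their groups do not overlap, which leaves the direction little room to change. Named changes that had not passed did so in 20 of 3673 comparisons.

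An adjusted p under 0.01 left 40 genes (seed-labelled), 92 (leaf-labelled), 25 (shared) and 10 (interaction), by its construction. Requiring both groups above background left 41 (seed-labelled), 17 (shared) and 19 (interaction), since it drops genes dim in one group. The fit of all 12 arrays gave 247 seed-labelled genes, 82 of them among the 87, and the cause was not tested. Without a filter 22 interaction genes passed, with more genes tested. With slide as a block the counts were 30, 89, 18 and 12, and the added slide terms gave 89 leaf-labelled genes and 114 seed-labelled ones. For the interaction the sizes held and the errors grew, while the cause of the other lower counts was not tested. The block and the slide terms give the same estimates, so they are not separate checks of each other.

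Replicate number as a block gave 54, 35, 16 and 15 genes, and 1 seed-labelled list, the SWEET genes (adjusted p = 0.0461, range over the alternatives 0.0461 to 0.937). Its adjusted p = 0.854 with an estimated correlation in the same fit. The numbers showed no pairing: residuals of arrays with the same number correlated across probes at -0.056, -0.165 and 0.059 (seed-labelled) and -0.152, -0.141 and -0.304 (leaf-labelled).

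Among seed-labelled lists, 1 passed with slide as a block and 1 with slide terms. In both it was the cytosolic ribosomal proteins, whose median turned from -0.05 to 0.17 (adjusted p = 0.0198 and 0.00161, range 0.00161 to 0.978), and adjusted p = 0.968 and 0.970 with an estimated correlation. Among leaf-labelled lists, 2 passed in the fit of all 12 arrays (abscisic acid response and amino acid transporters), 5 with slide terms (these, auxin response, core histones and ribosomal proteins), 1 with a variance trend (core histones) and 4 with slide as a block (core histones, amino acid transporters, auxin response, and peroxidases and glutathione transferases). Adjusted p ranged from 0.000344 to 0.632 for core histones, 0.0223 to 0.473 for the abscisic acid response, 0.0132 to 0.605 for amino acid transporters, 0.0264 to 0.959 for auxin response, 0.0341 to 0.993 for ribosomal proteins and 0.0449 to 0.959 for peroxidases and glutathione transferases. Of the list calls in these alternatives and without single replicates, 0 of 5 seed-labelled and 0 of 15 leaf-labelled ones held with the correlation estimated in the same fit (smallest adjusted p = 0.691 and 0.117 with an estimated correlation). The cause was not tested.

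Leaving out single replicates gave 45 to 102 seed-labelled genes (45 without line 51 replicate 2, 48 without its replicate 3), 84 to 128 leaf-labelled (84 without line 51 replicate 2, and 106 without WT replicate 1, line 51 replicate 1 or line 51 replicate 3) and 28 to 40 shared (28 without leaf-labelled line 51 replicate 2). The interaction count ran from 12 (without seed-labelled line 51 replicate 2) to 70 (without its replicate 1). It was 60 without seed-labelled WT replicate 1, and 21, 18 and 18 without leaf-labelled WT replicates 1, 2 and 3, and 16, 14 and 20 without leaf-labelled line 51 replicates 1, 2 and 3. Seed-labelled lists past the test ran from 0 to 1: starch synthesis without WT replicate 3, and storage proteins (5 genes, median 0.07) without line 51 replicate 3 (adjusted p = 0.964 and 0.691 with an estimated correlation). Leaf-labelled lists ran from 0 to 2: core histones without WT replicate 2, and core histones and the abscisic acid response without line 51 replicate 3 (adjusted p = 0.348, 0.946 and 0.637 with an estimated correlation). Fewer arrays lower the power, and the cause of the higher counts was not tested. Signal over background limits the size of the largest changes, since 40 seed-labelled and 42 leaf-labelled calls were dim in one group. Sizes also moved with the processing. Over the alternatives the seed-labelled log2 changes ran from 5.87 to 10.74 for Os05g0270500, 2.68 to 7.68 for Os01g0845900 and 5.94 to 8.61 for Os11g0224300. For the beta-expansin Os03g0106900 on leaf-labelled arrays they ran from 1.00 to 4.65. The smallest of these lie below the reported folds, those written as "at least" included.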

Other observations

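Of the tests below, those of exchanged tissue labels, of single exchanged arrays, of transposon names among the shared rises, and of other splits of the seed-labelled and of the leaf-labelled arrays were chosen after the result was seen. The test of missing descriptive names was not planned either.

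Probes that carry no locus were not counted as genes in the comparisons. Of 588 such probes, 238 were tested on seed-labelled and 222 on leaf-labelled arrays, most of them for microRNAs (213 and 200). By limma 0 passed under either label, with 38 and 22 at an unadjusted p under 0.05 and smallest adjusted p-values of 0.0606 and 0.174. Fewer genes with a descriptive name were among the 45 shared genes than among all genes tested: 27 (60%) had none, against 38.9% (Fisher's exact test, two-sided, p = 0.0053, odds ratio 2.36). This was not particular to the shared genes. Of all called genes, 48 of 87 seed-labelled and 108 of 160 leaf-labelled ones had no descriptive name.

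The seed-labelled arrays carried leaf transcripts and the leaf-labelled arrays floral ones. With a plain exchange of the labels the storage proteins would be abundant on the leaf-labelled arrays, whereas 19.4% of their genes were above background on all 6 and their median was -9.19 in WT. On the seed-labelled arrays the values were 11.1% and -9.67. The storage proteins thus go against the labels as given as much as against an exchange, and they cannot choose between them. An exchange of 1 or 2 arrays is argued against by the correlations, in which 12 of 12 arrays were closest to their own label. Young inflorescence RNA on the leaf-labelled arrays is a candidate explanation, in line with a median excess of 7.55 over 14 floral identity genes, MADS15 among them. Which tissue the seed-labelled arrays hold stays open, although photosynthesis genes at 5.88 on them are consistent with green leaf, and a biological effect of the day 10 stage was not tested.

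The shared changes in line 51 were very large, and many were of transcripts at background in WT. Between arrays of the same slide the smaller median change of these genes was 4.22, a size that a difference between slides alone would not give. It rests on 1 WT array of the leaf label. The genes were called on the same arrays, and a call needs the arrays of a group to agree across slides. Large changes within a slide were therefore favoured by the selection, and they speak for these genes only. A few chromosome segments that differ between the plants would give neighbouring genes, whereas 1 pair of the shared genes lay within 10 tested genes of each other (random sets: median 1, permutation p = 0.595), but 170 genes called under either label, a set examined after these results were seen, gave 23 pairs against a median of 13 (permutation p = 0.01). Sequence differences under single probes cannot be told apart from changed levels, since only 2 of the shared genes had a second probe with a separate sequence, and in 2 of 2 it moved the same way. Release of silenced transposons, another candidate explanation, was tested by names: 3 of 38 shared rises had transposon-related names against 105 of 21877 genes (Fisher's exact test, two-sided, p = 0.000802, odds ratio 18.3), and among genes that rose under 1 label only 2 of 92 did (p = 0.0723), so it stays open, as do a difference of seed stock and the insertion of the transgene itself, which were not tested.

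Other divisions of the arrays were counted for each comparison. The 6 arrays of a label can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. On the seed-labelled arrays 1 of the 10, the real one, gave 87 genes and the highest other gave 3. On the leaf-labelled arrays 1 of the 10, the real one, gave 160 and the highest other gave 0. For genes called under both labels, 1 of 100 assignments of genotype, the real one and others drawn at random, gave as many as 45. It was the real one, and the highest other gave 0, a share under 0.05. Other splits called at most 3 genes under a label, so other assignments had almost nothing to share. The count therefore excludes chance only against no genotype difference at all, not chance sharing between the calls of the labels.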
